A study of Mus musculus with 27 samples.

How the data were processed

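Whole brain RNA of 2 inbred mouse strains was measured on 2 array platforms. The labels describe 5 untreated C57 males and 4 untreated DBA mice, all 10 weeks old, and do not give the sex of the DBA mice. They write the strains as C57BL/2 and DBA/2J. Labelled cRNA was prepared from 5 ug of total RNA per the labels' protocol, with a column kit meant for fatty tissue and the array maker's usual procedure. One platform has 9 arrays titled with a strain and a number (unlettered arrays, 5 C57 and 4 DBA). The other has 18 arrays whose titles add a letter A or B to the number (lettered arrays, 10 C57 and 8 DBA). Each number was taken as 1 animal, because the numbers run to 5 and 4 as the animals do, and arrays A and B of a number were averaged as log2 values. The labels do not say what the letters stand for, or whether a number is the same animal on both platforms. Every sample's description also carries the alternative name C57 1, DBA samples included, so groups were taken from the titles.

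Both deposited tables hold intensities on a linear scale. The scanner software, the summary of probes into probe sets and the normalization are not given in the sources used here. In the deposited intensities of the unlettered arrays, the mean without the top and bottom 2% of values was 500.3 on all 9 arrays, so each array had been scaled to 1 target. In the deposited intensities of the lettered arrays, the median of each array lay between 0.915 and 0.947, some values were just below 0, and a fixed code stood for no value. No detection call or background value was used here, and the number of arrays limits the precision.

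The unlettered table has 12488 probe sets, of which 66 are array controls. A platform annotation gave 1 gene symbol to 10855 probe sets, several to 396 and none to 1237. Symbols were updated through gene identifiers for 10839 of them with the RefSeq gene table of assembly GRCm38.p6, and 8252 genes were named. Probe sets with several symbols or none were tested without a name. The lettered table has 10500 numbered probes, of which 9943 had a value on every array. Its listed names were not used, for a reason measured in the results, and its probes are given by number.

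Intensities under the 1st percentile of positive values (1.70 on the unlettered and 0.0109 on the lettered arrays) were raised to it, which moved 1.08% and 1.76% of the values, and log2 was taken. Array medians of log2 values spanned 0.31 on the unlettered and 0.05 on the lettered arrays, under the limit of 0.5 set for adding quantile normalization, so the scaling was left as deposited. The dimmest 25% of probes by mean over all arrays of a platform were left out. The limit on the unlettered arrays was an intensity of 35.4. This left 9316 probe sets (6864 named genes) and 7457 lettered probes. Strains were compared per platform by lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, as DBA minus C57, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Adjusted p-values below are from this fit unless another test is named. Folds are ratios of geometric mean intensities, and ± gives the standard error of a log2 difference. Figures were drawn with matplotlib 3.10.9.

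The design, the gene lists, the naming rule and most alternatives were set before the data were examined. Named genes are, among probe sets past the threshold with 1 symbol and no overlap between the strains, the 10 with the largest rise and the 10 with the largest fall in DBA, 1 probe set per gene and direction. From each list, up to 4 members past the threshold were named, or the member with the smallest p where none passed, and all measured members of the strain variant and sex-linked lists. Genes named outside this rule are marked as chosen after their values were seen. The 25 lists cover known C57 and DBA differences, neurotransmission, metabolism, cell types, regions, blood, sex and stress. Lists with at least 5 tested genes (23 lists) were tested on the unlettered arrays with camera of limma at a preset correlation of 0.01, with the brightest probe set per gene. Camera with an estimated correlation and fry were run beside it. Counts of members past the threshold use the brightest probe set of a gene unless another is named, with p adjusted over all probe sets tested or over the list alone.

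For the lettered arrays, the SD between arrays A and B of a number was set against the SD between animals, taken on the means of A and B. The B arrays were permuted within strain (2880 pairings, exact, 1-sided). RNA quality was measured as the log2 ratio of the 3' to the 5' control probe set of 4 control genes and compared by an exact 2-sided permutation test. Other splits of the 9 animals into 5 and 4 were drawn (100 splits, the real one included). The alternatives were other scaling, other floors, other filters on dim probes, another variance model, the number as a block, single letters, 1 probe set per gene, a stricter threshold, and leaving out each animal in turn. Batches of lettered arrays were presumed from counts of missing values alone, since the labels name none, and fits with them as a block and within the first were added after seeing the data; in both the DBA side of the comparison is 1 animal. Members of lists called at a dimmer probe set were also looked up after seeing the data. The planned comparison of gene-level changes between the platforms, and lists and named genes on the lettered arrays, were not carried through because names and numbers did not pair.

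The fits were tested on simulated data built from the real means and spreads. On the unlettered arrays, 28.4%, 79.1% and 93.9% of probe sets changed by 0.5, 1 and 2 log2 units were called, and 4.29% of calls were false. On the lettered arrays these shares were 53.7%, 95.5% and 97.0%, with 8.38% false. Neither batches of arrays nor shifts along the probe numbers were simulated, so this false share does not carry over to the real lettered calls. A list of genes all moved by a fixed amount on the simulated unlettered arrays reached a camera adjusted p of 0.000191. The simulated genes varied independently of each other, so this does not test camera on genes that vary together.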

Results

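RNA levels were measured in whole brains of 2 inbred mouse strains, C57 and DBA, at 10 weeks of age and without treatment. The unlettered arrays covered 5 C57 and 4 DBA animals with 1 array each. The lettered arrays covered as many animal numbers with a pair of arrays each, 10 for C57 and 8 for DBA. Median intensity ran from 160 to 198 on the unlettered arrays, and any pair of these arrays correlated at 0.945 to 0.970 across probe sets, which are not independent replicates. The question was how the brain expression pattern differs between the strains.

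Gnb1, which encodes a beta subunit of heterotrimeric G proteins, was among the genes with the largest rise in DBA brain on the unlettered arrays. Its probe set 97458_at was 16.9-fold higher (log2 difference 4.08 ± 0.16, mean intensity 461 in 5 C57 and 7772 in 4 DBA animals, adjusted p = 2.31e-06), and its other tested sets were 6.45-fold (94854_g_at) and 4.62-fold (94853_at) higher. Pam, which encodes the enzyme that amidates neuropeptides, rose 17.1-fold (4.09 ± 0.50, adjusted p = 0.00157). Its C57 animals spread widely, from a log2 intensity of 4.49 in animal 1 to 7.32 in animal 3. Without C57 animal 1 the log2 difference of Pam was 3.65. Cap1, an actin-binding protein first known as a partner of adenylyl cyclase, rose 7.39-fold (2.89 ± 0.13, adjusted p = 4.78e-06). The MHC class I gene H2-D1 rose 5.75-fold by probe set 97541_f_at (2.52 ± 0.14, adjusted p = 1.09e-05) and 2.23-fold by 97540_f_at, while 101886_f_at differed by 0.17 ± 0.09 (adjusted p = 0.517). Sdf4, a calcium-binding protein of the Golgi, rose 4.58-fold (2.19 ± 0.35, adjusted p = 0.00650). Pam, Cap1 and Sdf4 had no other tested probe set to set beside these values.

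Other large rises rested on a C57 level below the brightness limit of 35.4 or on 1 of several probe sets. AI506816 (93180_at) had a mean intensity of 17.7 in C57 and 168 in DBA (adjusted p = 0.00166), while its set 97197_r_at differed by -0.37 ± 0.25 (adjusted p = 0.635). Serpina1b, of the alpha-1-antitrypsin family, had 34.7 and 175 (101576_f_at, adjusted p = 0.00284). This set, the only tested one of Serpina1b, ends in f_at, a suffix of sets that match families of similar sequences. Cbfa2t2, a transcriptional corepressor, had 24.2 and 106 by 98371_at (adjusted p = 0.00173) and differed by 0.07 ± 0.12 by 97406_at. The transcription factor gene Klf13 rose 4.66-fold by 103369_at (2.22 ± 0.43, adjusted p = 0.0233) and differed by -0.21 ± 0.10 by 160617_at. The Klf13 call was lost without C57 animal 1, 3 or 4 or DBA animal 2, with adjusted p of 0.0599, 0.0598, 0.0632 and 0.0563. The probe sets named Pdxdc1, a predicted decarboxylase, went both ways. 97713_at was at 14.5 in C57, below the brightness limit, and at 1605 in DBA (adjusted p = 5.49e-06), whereas 160163_at was 12.1-fold lower (-3.60 ± 0.36, adjusted p = 0.000505) and 94312_at 5.12-fold lower in DBA. No direction of the whole gene follows from these 3 sets.

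The largest falls in DBA included Thumpd1, a cofactor of tRNA acetylation, which was 8.87-fold lower (-3.15 ± 0.16, adjusted p = 7.37e-06; mean intensity 1214 in C57 and 137 in DBA). Spg21, which encodes maspardin, was 8.02-fold lower (-3.00 ± 0.23, adjusted p = 6.63e-05), and the small nucleolar RNA host gene Snhg6 was 7.78-fold lower (-2.96 ± 0.17, adjusted p = 1.09e-05). Aldh9a1, an aldehyde dehydrogenase that oxidizes aminoaldehydes, was 5.61-fold lower (-2.49 ± 0.23, adjusted p = 0.000244). The probe set listed for the microRNA gene Mir686 was 5.38-fold lower (-2.43 ± 0.16, adjusted p = 2.93e-05). Usp38, a deubiquitinase, was 5.05-fold lower by 160605_s_at (adjusted p = 1.76e-05) and 1.51-fold lower by 102776_at (adjusted p = 0.0333). Tbc1d15, a Rab GTPase activator, was 5.12-fold lower by 103471_at (-2.36 ± 0.18, adjusted p = 6.63e-05) and differed by 0.07 ± 0.12 by 104283_at. The DBA level was below the brightness limit for Sspn, a dystrophin-complex protein (247 in C57, 30.7 in DBA, adjusted p = 0.00388), and for the splicing factor gene Snrpb2 by 92839_f_at (137 and 21.5, adjusted p = 0.0114). At this Snrpb2 set DBA animal 1 had a log2 intensity of 2.66 against 4.71 to 5.31 in the other DBA animals, and the log2 difference moved from -2.67 to -2.08 without it. The other Snrpb2 set, 162026_r_at, differed by -0.25 ± 0.23 (adjusted p = 0.765). Thumpd1, Spg21, Snhg6, Aldh9a1, Mir686 and Sspn had no other tested probe set to set beside these values. Where called genes had other tested sets, these followed a lower call in 21 of 62 cases and a higher call in 25 of 42. To follow meant to go the same way at an unadjusted limma p under 0.05. A fall at a single set therefore does not settle the RNA level of its gene. The sets of Spg21 (95430_f_at), Aldh9a1 (96243_f_at) and Snrpb2 (92839_f_at) also end in f_at and may match similar sequences of other genes.

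**Figure D1:**
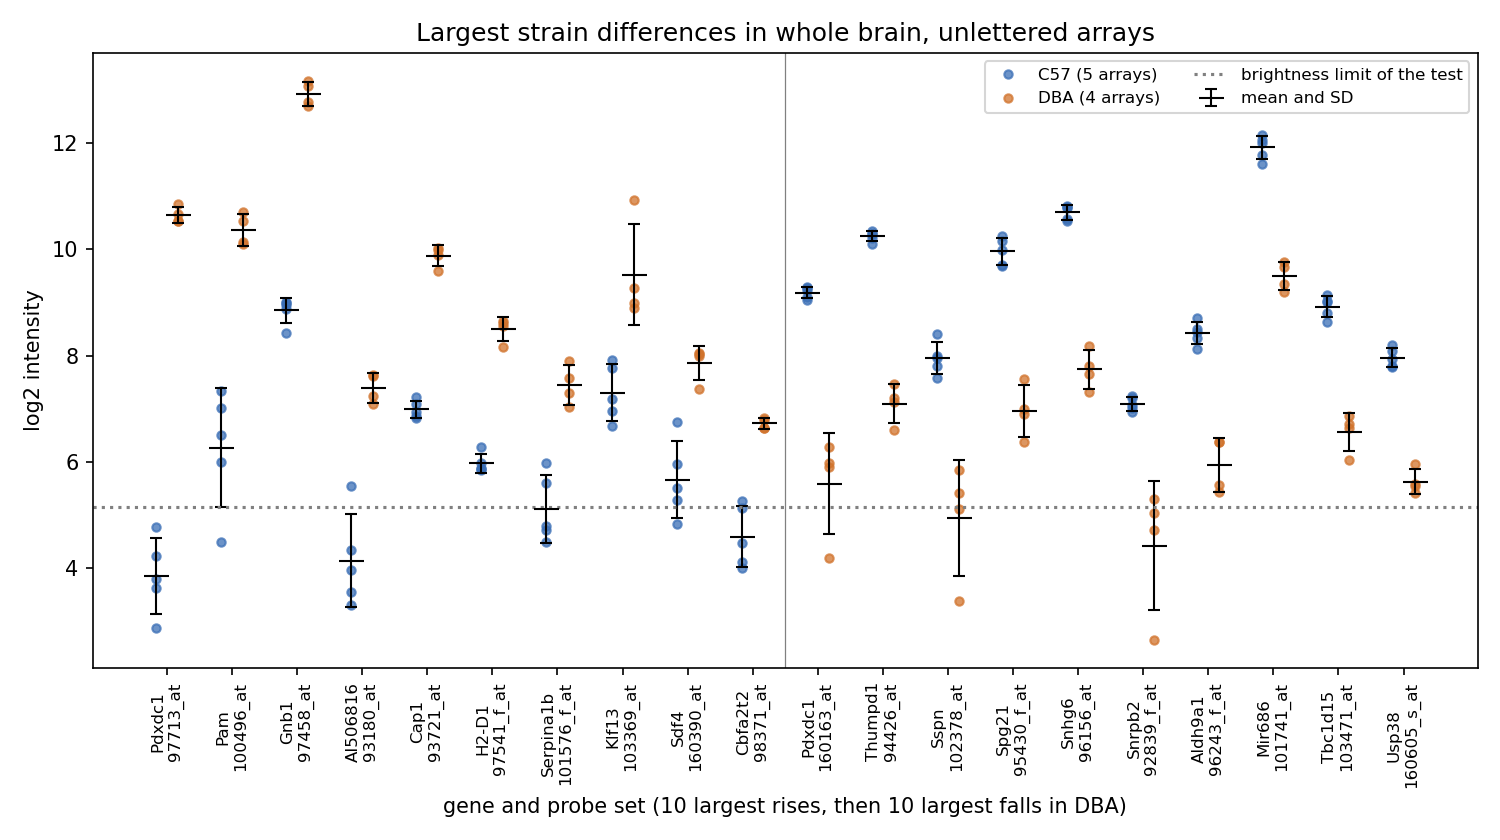
Log2 intensity of the 10 probe sets with the largest rise and the 10 with the largest fall in DBA, by probe set (horizontal axis). Points are single arrays (5 C57, 4 DBA), bars give mean and SD, and the dotted line is the brightness limit of the test. The strains do not overlap at any of these sets, and 4 rises and 2 falls have 1 strain's mean below the limit.

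Over all probe sets, 233 of 9316 tested (2.50%) differed between the strains, 83 higher and 150 lower in DBA. The share of lower calls was 64.4% (exact binomial 95% interval 57.9 to 70.5). This interval takes probe sets as independent, which sets of the same animals and genes are not. More than 2-fold changes were found at 37 sets higher and 76 lower in DBA. At all 233 called sets the C57 and DBA animals did not overlap. Such separation was seen at 601 tested sets (6.45%), against 1.59% by chance for 5 and 4 animals. The 205 called sets with 1 symbol stood for 192 genes, 62 of them higher, 129 lower and 1, Pdxdc1, both. With 1 probe set per gene, 154 of 6864 genes were called, 53 higher and 101 lower. At an adjusted p under 0.01, 150 sets remained called.

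Among genes chosen beforehand as known to differ between these strains or their relatives, 6 of 13 tested passed the threshold by the brightest probe set of each gene, 5 higher and 1 lower in DBA, or 5 higher and 3 lower adjusted over the list alone. H2-D1 passed at dimmer sets only, as given above, which makes 7 genes. Besides Gnb1, the rises were Alad, the second enzyme of haem synthesis (3.24-fold, 1.70 ± 0.12, adjusted p = 5.32e-05), Kcnj9, a G protein-gated potassium channel subunit (2.71-fold, 1.44 ± 0.12, adjusted p = 0.000147), Glo1, which detoxifies methylglyoxal (2.14-fold by 93269_at, adjusted p = 0.000842), and H2-K1 (0.58 ± 0.12 by 93120_f_at). The other Kcnj9 set, 161799_r_at, differed by 0.65 ± 0.27 (adjusted p = 0.358), and the other Glo1 set, 93268_at, by 0.74 ± 0.18 (adjusted p = 0.0670, or 0.0124 without DBA animal 3). Pttg1, which encodes securin, was 3.07-fold lower (-1.62 ± 0.13, adjusted p = 0.000105). Log2 differences of members that did not pass were 0.02 ± 0.10 for Cox7a2l, -0.12 ± 0.25 for Gabra2, 0.29 ± 0.19 for Hebp1, -0.26 ± 0.18 for Nnt and -0.62 ± 0.21 for Myo5a. Mpdz differed by -0.55 ± 0.16 at 93887_at (adjusted p = 0.159, or 0.0183 without C57 animal 4), by 0.05 ± 0.23 at 100728_at and by -0.35 ± 0.24 at 161708_f_at. The probe sets of Hc, Klrd1 and Tyrp1 lay below the brightness limit. As a whole this list ranked higher in DBA than other genes (camera adjusted p = 0.0236, median 0.17), with adjusted p = 0.217 with an estimated correlation. The list was no longer past the threshold without C57 animal 4, DBA animal 1 or DBA animal 4 (camera adjusted p of 0.0875, 0.0919 and 0.0641).

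MHC and antigen presentation genes ranked higher in DBA, with 10 of 12 tested members above 0 and a median log2 difference of 0.20 (camera adjusted p = 0.00993; adjusted p = 0.217 with an estimated correlation). By the brightest probe set of each gene, 1 member passed, adjusted over all probe sets or over the list alone: H2-K1 by 93120_f_at (0.58 ± 0.12, adjusted p = 0.0346). By any set 2 members passed, since H2-D1 was called at 97541_f_at and 97540_f_at but not at its brightest set, 101886_f_at. The H2-K1 set 97125_f_at was 2.13-fold higher (adjusted p = 0.0102) and 97700_at differed by -0.30 ± 0.21. The call of 93120_f_at was lost without C57 animal 1, 3, 4 or 5 or DBA animal 1, 2 or 4 (adjusted p 0.0627 to 0.116) and with arrays centred on their median (adjusted p = 0.157). The probe sets of H2-D1 and H2-K1 ending in f_at match families of similar sequences, and do not separate all class I genes. Both genes are also members of the strain variant list, so the calls of the MHC and strain variant lists are not independent.

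Immediate early genes, which neurons switch on within minutes of stimulation, ranked higher in DBA, with 12 of 14 members above 0 and a median of 0.30 (camera adjusted p = 0.0107; adjusted p = 0.599 with an estimated correlation). The list missed the threshold without C57 animal 4 (camera adjusted p = 0.0579). With 1 animal left out, its median ran from 0.20 (without DBA animal 4) to 0.39 (without C57 animal 1). By the brightest probe set of each gene, Btg2 passed adjusted over all probe sets (1.44-fold, 0.53 ± 0.11, adjusted p = 0.0432), and 3 members passed adjusted over the list alone. Junb passed at a dimmer set, 102362_i_at (0.91 ± 0.18, adjusted p = 0.0285), and differed by 0.39 ± 0.20 at its brightest, 102363_r_at (adjusted p = 0.478). The Junb call was lost without C57 animal 1 or 3 or DBA animal 1, 3 or 4 (adjusted p 0.0592 to 0.0986), and without a filter on dim probe sets (adjusted p = 0.0608). The Btg2 call was lost without C57 animal 2, 3, 4 or 5 or any 1 of the DBA animals (adjusted p 0.0553 to 0.142), and with median centring (adjusted p = 0.0733). Oligodendrocyte genes ranked lower in DBA, with 7 of 9 members below 0 and a median of -0.36 (camera adjusted p = 0.00993, or 0.599 with an estimated correlation). With 1 animal left out, the median of this list ran from -0.54 (without C57 animal 2) to -0.29 (without C57 animal 5). By the brightest probe set of each gene, limma called 0 members, 4 had an unadjusted p under 0.05, and 3 passed adjusted over the list alone. The smallest p was that of Mag, a myelin adhesion protein (-0.57 ± 0.16, adjusted p = 0.120). Mobp, which encodes a basic protein of myelin, passed at 99046_at (-0.84 ± 0.12, adjusted p = 0.00416) and differed by -0.11 ± 0.19 at 100536_at, its brightest, by -0.22 ± 0.16 at 99047_at and by -0.35 ± 0.13 at 99048_g_at. These 4 lists were the calls of camera among 23 lists, and 0 were called with an estimated correlation, where 2 had an unadjusted p under 0.05. Fry, tested for members that move 1 way, called 3 lists, the strain variant and MHC lists and that of alcohol and aldehyde metabolism. Its mixed test, which asks for differences of members in either direction, called 15 of the 23 lists. Neither test compares a list with other genes. Of 100 splits of the 9 animals, 12 gave as many lists as the strains.

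Lists of neurotransmission were not called as wholes by camera, with few single genes that differed. Slc32a1, the vesicular transporter that loads GABA and glycine, was 3.38-fold lower in DBA (mean intensity 5490 in C57 and 1623 in DBA, -1.76 ± 0.26, adjusted p = 0.00416) and was the 1 called member of 14 GABA genes, also adjusted over the list alone. Of the glutamate list 0 of 19 members passed, of the monoamine and acetylcholine list 0 of 18, and of the neuropeptide and opioid list 0 of 19, by limma adjusted over all probe sets or, by the brightest sets, over the list alone. At an unadjusted p under 0.05, 4, 2 and 1 members passed in these lists in that order. The smallest p of each list was that of Gria1 (0.41 ± 0.13), Chrm4 (mean intensity 57.5 in C57 and 25.5 in DBA, the latter below the brightness limit) and Adcyap1 (-0.43 ± 0.19). Of 21 potassium channel genes, Kcnj9 rose and Kcnj11, a subunit of the ATP-sensitive channel, was 1.60-fold lower (-0.68 ± 0.12, adjusted p = 0.0135, or 0.0531 without DBA animal 1), with the same counts adjusted over the list alone.

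Of the metabolic lists, that of alcohol and aldehyde enzymes had 2 of 11 members lower in DBA, Aldh9a1 and Aldh7a1 (1.62-fold, -0.70 ± 0.12, adjusted p = 0.00925, or 0.0503 with median centring). The other Aldh7a1 set, 97449_at, differed by -0.65 ± 0.14 (adjusted p = 0.0452), and this call was lost without any 1 animal other than C57 animal 3 (0.0603 to 0.114) and with quantile normalization (0.0512) or median centring (0.149). Adjusted over the list alone, Aldh1a2 was higher as well (1.19 ± 0.36). Of 41 oxidative phosphorylation genes 1 was lower, Ndufa7 (1.60-fold, -0.68 ± 0.13, adjusted p = 0.0233), adjusted over all probe sets or over the list alone. The Ndufa7 call was lost without C57 animal 2, 4 or 5 or DBA animal 1, 2 or 4 (adjusted p 0.0530 to 0.0758) and with median centring (adjusted p = 0.105). Among 25 glutathione and redox genes 0 passed by the brightest probe set of each gene adjusted over all probe sets, and 1 higher and 2 lower passed adjusted over the list alone, led by Gsr (0.49 ± 0.12, adjusted p = 0.0771). Prdx2, a peroxiredoxin, passed at a dimmer set, 99608_at (-1.85 ± 0.10, adjusted p = 1.09e-05), and differed by 0.07 ± 0.10 at its brightest, 100331_g_at (adjusted p = 0.849). Of 22 ribosomal protein and 11 heat shock genes 0 passed either way, and the smallest p were those of Rps7 (0.32 ± 0.12) and Hspa1a (-0.47 ± 0.17). The heat shock list was called lower by camera without C57 animal 3 (adjusted p = 0.0482). With all animals its camera adjusted p was 0.134, or 0.599 with an estimated correlation. At an unadjusted p under 0.05, 3, 2 and 2 members of the redox, ribosomal and heat shock lists passed in that order by their brightest sets.

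Of the cell type lists, microglia had 2 of 12 members lower in DBA, the complement genes C1qb (1.81-fold, -0.85 ± 0.12, adjusted p = 0.00343) and C1qc (1.57-fold, -0.65 ± 0.13, adjusted p = 0.0318), also adjusted over the list alone. The other C1qb set differed by -0.58 ± 0.31 (adjusted p = 0.517). The C1qc call was lost without C57 animal 2, 4 or 5 or DBA animal 1, 2 or 3 (adjusted p 0.0525 to 0.104) and with median centring (adjusted p = 0.106). Of 12 interferon-response genes, Gbp2 was 1.72-fold higher (0.78 ± 0.14, adjusted p = 0.0159, or 0.0607 and 0.0550 without DBA animal 1 or 2), and Irgm1 was lower adjusted over the list alone. Adjusted over all probe sets, 0 members passed at any set of 16 neuron, 14 astrocyte, 14 vascular, 6 choroid plexus and ependyma, 5 blood, 7 pituitary, 11 cerebellum and 4 striatum genes. By the brightest sets adjusted over the list alone, 4 vascular genes (1 higher, 3 lower), 2 blood genes (1 higher, 1 lower) and 1 cerebellum gene (higher) passed. At an unadjusted p under 0.05, 3, 3, 4, 2, 2, 0, 1 and 0 members passed in the order of these 8 lists. Their smallest p were those of Syn2 (0.27 ± 0.09), Glul (-0.54 ± 0.16), Myh11 (0.66 ± 0.20), Ttr (0.85 ± 0.30), S100a8 (-1.01 ± 0.23, adjusted p = 0.0506), Ghrhr (0.53 ± 0.32), Cbln1 (0.40 ± 0.10) and Penk (-0.17 ± 0.12). The cerebellum list was called higher by camera without DBA animal 3 (adjusted p = 0.0110). With all animals its camera adjusted p was 0.134, or 0.599 with an estimated correlation. Of the sex-linked genes, Y-linked Eif2s3y differed by 0.07 ± 0.14 and Uty by -0.63 ± 0.31 (adjusted p = 0.901 and 0.461). The Eif2s3y set, 103674_f_at, ends in f_at and may match similar sequences besides the Y-linked gene. Xist, which silences an X chromosome in females, lay below the brightness limit in both strains (26.5 in C57 and 21.4 in DBA), as did Kdm5d.

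**Figure D2:**
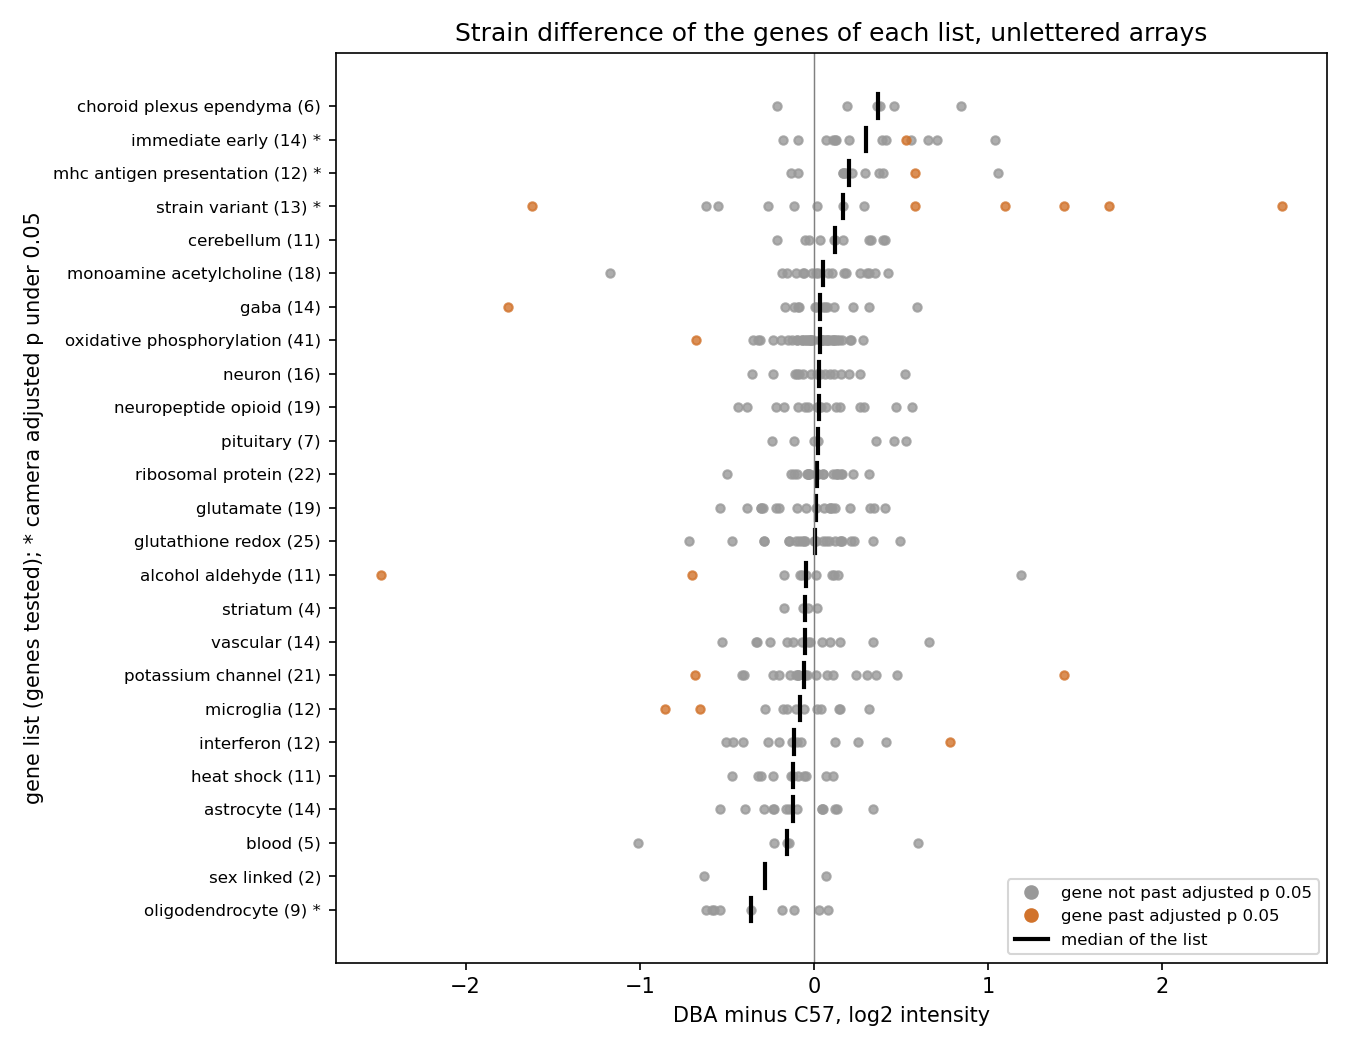
Log2 difference, DBA minus C57, of each tested gene (points, brightest probe set) of the 25 lists, with the number of genes tested and the median (black bar), on the unlettered arrays. Coloured points passed an adjusted p of 0.05 over all probe sets, and stars mark the 4 lists called by camera. Medians run from -0.36 (oligodendrocyte) to 0.37 (choroid plexus and ependyma, camera adjusted p = 0.134).

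The log2 ratio of 3' to 5' control probe sets, a measure of RNA integrity and labelling, was lower in DBA for all 4 control genes, with differences of -0.12 (Gapdh), -0.13 (beta-actin), -0.32 (pyruvate carboxylase) and -0.14 (transferrin receptor). Exact permutation tests gave p = 0.0159, 0.159, 0.0556 and 0.135, or 0.0635, 0.159, 0.111 and 0.159 after Benjamini-Hochberg adjustment. The strains did not overlap for Gapdh, and its p is the smallest that 5 and 4 animals allow, which cannot pass alone after adjustment over 4 genes. A strain difference in RNA quality therefore stays open. The median strain difference over all tested probe sets was 0.01 as deposited.

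On the lettered arrays the strains differed at 2514 of 7457 probes (33.7%), 1129 higher and 1385 lower in DBA. Probe 8533 was 135-fold higher in DBA (7.07 ± 0.11, adjusted p = 9.69e-13). For the others named, 1 strain lay below the brightness limit of these arrays, an intensity of 0.177, so no fold is given. Probe 5481 had a mean intensity of 0.0376 in C57 and 1.60 in DBA (adjusted p = 3.49e-08), probe 2482 had 7.52 and 0.132 (adjusted p = 2.28e-10), and probe 2732 had 6.73 and 0.176 (adjusted p = 1.00e-11). Counts of missing values split these arrays in a way that follows the strains in part, and the labels name no batch. On all arrays of the C57 animals and DBA animal 1 between 315 and 345 probes had no value, against 24 to 78 on those of DBA animals 2 to 4. Taken as batches, the second holds DBA animals only, so with the presumed batch as a block the strain difference is that of DBA animal 1 against the C57 animals, and DBA animals 2 to 4 add only to the estimate of the spread. This fit called 1036 probes (494 higher, 542 lower). Within the first presumed batch alone 1736 were called (787 higher, 949 lower), with the lone DBA animal assumed to vary like the C57 animals. In both, the DBA side rests on 1 animal. Probe 8533 differed by 6.86 ± 0.16 with the block. Differences from C57 also shifted along the probe numbers. Medians over bins of 500 numbers ranged over 0.64 log2 units for DBA animal 3, 0.43 for 2 and 4 and 0.35 for 1. A C57 animal against the others reached up to 0.40, and the median size of the called changes was 0.52. Arrays of different animals correlated at a median of 0.957 between presumed batches, and at 0.977 and 0.972 within the first and second. Most pairs between batches also differ in strain.

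**Figure D3:**
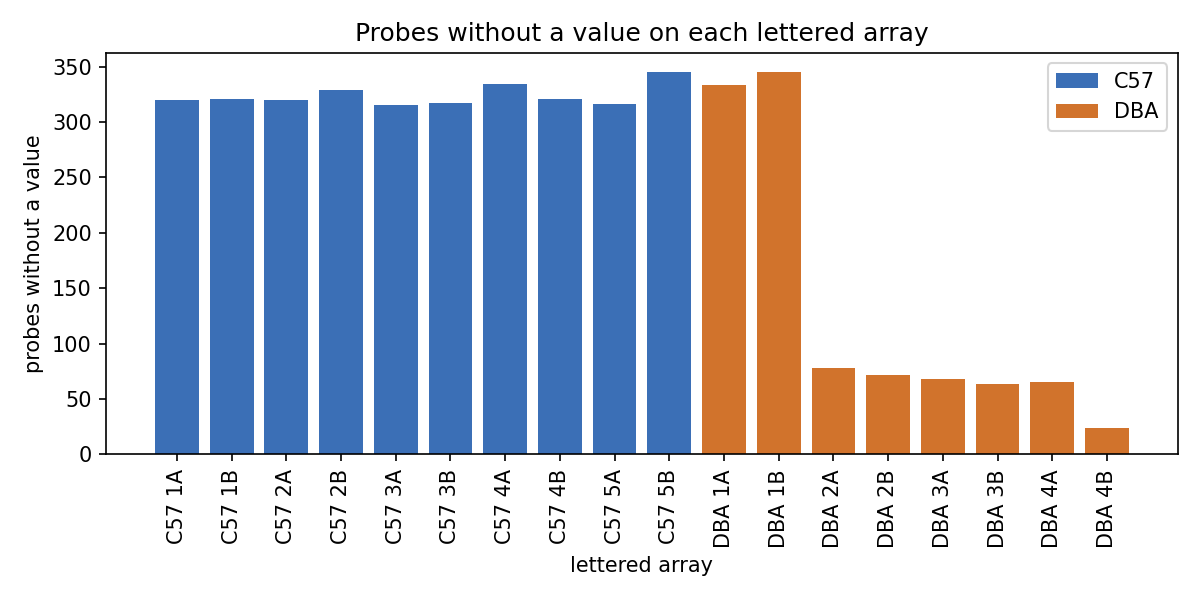
Number of probes without a value on each of the 18 lettered arrays (bars, C57 and DBA). Arrays of DBA animal 1 lie with those of the C57 animals at 315 to 345 probes, and arrays of DBA animals 2 to 4 at 24 to 78.

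Levels on the lettered arrays did not follow those of the same listed gene on the unlettered arrays. Over 5521 genes named on both, mean log2 levels correlated at r = 0.00264 (Spearman 0.00245), and random pairings gave an SD of 0.0130. Of 7 genes at percentiles 97.7 to 99.9 of the unlettered arrays (Snap25, Aldoc, Apoe, Thy1, Syt1, Tubb3 and Hspa8, chosen after their values were seen), Apoe lay at 91.9 on the lettered arrays as listed and the others at 6.39 to 35.2. Strain differences of 3502 genes tested on both correlated at r = -0.0158 (Spearman -0.0110). Of 24 genes called on both, 11 had the same direction, against 13.1 for independent lists. Correlations over genes describe these arrays, since genes are not independent replicates. The listed names were therefore not attached to lettered probes, and whether the platforms give the same strain differences was not determined.

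Arrays A and B of 1 number deviated together from the mean of their strain, with a mean correlation of 0.546 over 9 animals (range 0.339 to 0.699) against -0.139 for arrays of different numbers. The exact 1-sided permutation test gave p = 0.000347, the smallest that 2880 pairings allow. These pairings mix DBA animal 1 with DBA animals 2 to 4, so this value does not separate the animals from the presumed batches. Without DBA animal 1 the mean correlation was 0.538 against -0.150, and p = 0.00139 was the smallest that 720 pairings allow. The median SD was 0.13 log2 units between arrays A and B and 0.18 between animals of a strain, a ratio of 1.39. The first is the SD of a single array and the second that of the means of arrays A and B. Averaging lowers array error, so this ratio would lie below 1 if animals did not differ and arrays A and B shared no technical error. Whether they shared any is not known, since the labels do not explain the letters. Within C57 animals, all in 1 presumed batch, these SDs were 0.12 and 0.14, and within DBA animals 0.11 and 0.20.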

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

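The tests of sequence variants, of a presumed array batch and both tests on gene names, and the fit with that batch as a block, were chosen after the results they address had been seen. The others were planned.

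More probe sets were lower than higher in DBA on the unlettered arrays (150 against 83 of 233 calls). Of 100 splits of the animals, 1, the real one, gave as many calls, and the highest other gave 2. The strain split thus had the most calls of those drawn, which argues against a split without any strain difference. Every other split leaves both strains on at least 1 side, which widens the spread and lowers its calls. Their counts therefore do not tell how many of the 233 calls are false. The other splits had too few calls to give a share of lower calls, so they do not test the direction. Scaling of the arrays is argued against: under quantile normalization and median centring the share of lower calls was at least 65.3% (exact 95% interval from 58.9). So is noise of dim probe sets, since the share was 65.3% (interval from 59.1) among the brighter probes. Both intervals take probe sets as independent, which sets of the same animals and genes are not. Sequence variants of DBA under probes designed on another sequence could lower single probe sets. Other sets of the same gene followed a lower call in 21 of 62 cases and a higher call in 25 of 42 (Fisher's exact p = 0.0153). A set followed when it went the same way at an unadjusted p under 0.05. Called sets of 1 gene, such as those of Gnb1, each count as following the others. The cases are therefore not independent, and the p decides little. A true excess of genes with lower RNA in DBA brain stays open and was not tested.

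The lettered arrays of DBA animals 2 to 4 stood apart from those of DBA animal 1, which lacked values at 339 probes on average of its arrays A and B, against 44.5 to 75 for the other DBA animals. Of the 314 probes that lacked a value on every C57 array, 100% lacked one on both arrays of DBA animal 1 as well, but these missing values are the pattern itself and do not favour a batch of arrays over a difference between the animals. The 2 cannot be told apart here, since the labels name no batch and do not tie numbers between platforms. Limma called 0 probe sets between DBA animal 1 and animals 2 to 4 on the unlettered arrays, with 422 (4.53%) at an unadjusted p under 0.05, and 44 and 1236 (16.6%) on the lettered arrays, but 1 side is a single animal and the spread comes from the other animals, so these counts decide little. The 2514 strain calls were reached by 1 of 100 splits, the real one, and the highest other gave 42. Every other split leaves both strains on at least 1 side, which widens the spread and lowers its calls. The real split also follows the presumed batches in part. The splits therefore do not tell how many of the 2514 calls are due to strain. With the presumed batch as a block, the calls rest on DBA animal 1 alone for that strain.

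Levels of genes named on both platforms did not correlate (r = 0.00264 against an SD of 0.0130 over random pairings). Measurement noise is argued against, since the lowest correlation of any 2 arrays of a platform was 0.929. That the probe numbers of the lettered table do not pair with the listed names is consistent with the same r. No biological explanation was tested, as the design gives none.

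The 4 lists called by camera cannot be set apart from chance: 12 of 100 splits gave as many, and the highest other split gave 7.

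A single animal stood apart from the others of its strain in 7 of 102 sets of values checked, where chance gives about 1 in 20. The measure was the gap to the nearest animal over the range of the strain, against the 95% critical value of Dixon for 4 or 5 animals, so a wide gap does not count where the others of the strain spread as well (Snrpb2 of DBA animal 1, and Klf13 of DBA animal 3 at 10.93 against 8.89 to 9.27). C57 animal 1 had a log2 intensity of 8.42 for Gnb1 (97458_at) against 8.87 to 9.01 in the other C57 animals. C57 animal 4 had 6.29 for H2-D1 (97541_f_at) against 5.85 to 5.97. DBA animal 3 had 7.37 for Sdf4 against 7.98 to 8.05 in the other DBA animals, 10.20 for H2-K1 (93120_f_at) against 10.49 to 10.54, and a Gapdh 3' to 5' log2 ratio of -0.44 against -0.34 to -0.32. DBA animal 4 had 9.34 for Aldh7a1 (97449_at) against 9.50 to 9.51. The count of missing values of DBA animal 1 given above was the other one. Outside the tested probes, 309 of the 314 probes without a value on the 12 arrays of the first presumed batch had one on all 6 arrays of the second, and 133 of them (43.0%) lay above the median there.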

How the results depend on the processing

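The fits with the presumed array batch, and the SD ratio within C57, were added after seeing the data. No result changed direction past the threshold under any setting run. On the unlettered arrays the count of calls (233) lay between 203 and 296 under other scaling, floors, filters and variance model, and between 184 and 228 with 1 animal left out. It was 154 with 1 probe set per gene and 150 at an adjusted p under 0.01, by construction. With a replicate block it was 73; same-numbered C57 and DBA arrays correlated at -0.10, -0.02, -0.01 and -0.17 after strain means were removed, and on the lettered arrays at 0.02, -0.06, -0.10 and 0.31, so the numbers did not pair the strains, and 1 of 8 DBA samples correlated best with its own number. The replicate block gave 2233 lettered calls and 3 lists.

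On the lettered arrays the count (2514) fell to 1675 in the brighter part of the probes (fewer probes tested), 1393 at an adjusted p under 0.01, and 1036 with the presumed batch as a block, where the DBA side is 1 animal by construction. Without 1 animal it ran from 1739 to 3327. Of the gene lists (4), 0 were called with an estimated correlation by camera, against 4 at the preset one and 3 by fry, and 2 had an unadjusted p under 0.05. Without 1 animal 2 to 5 were called, the 2 without C57 animal 4. The ratio of the SD between animals to that between arrays A and B (1.39) was 1.19 within C57 and 1.26 to 1.53 without 1 animal. The cause was not tested where none is given.

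Calls of named probe sets were lost in 53 and gained in 2 of their refits without 1 animal, and lost in 47 and gained in 2 of their other refits. List calls were lost in 4 and gained in 2, and lost in 7 and gained in 1. The alternatives for comparing genes between platforms, and 1 probe per gene on the lettered arrays, were not run because names did not pair with probes. Without background values, how far signal lay above background is not known.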

Other observations

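The test of neighbouring genes was planned, and the genes named here were chosen after their values were seen. Called genes were neighbours on a chromosome in 14 pairs, and those pairs that hold a gene named in the report are given here. Slc32a1 and the small nucleolar RNA host gene Snhg11 were both lower in DBA (log2 differences -1.76 ± 0.26 and -1.97 ± 0.15, adjusted p = 0.00416 and 7.27e-05), while the GABA-synthesizing enzymes Gad1 and Gad2 differed by 0.01 ± 0.13 and 0.22 ± 0.24. Thumpd1 and Eri2 were both lower (-3.15 ± 0.16 and -0.54 ± 0.09), Eri2 with adjusted p = 0.0134, or 0.0786 with median centring. The other pairs given here went apart. Aldh9a1 was lower (-2.49 ± 0.23) and Mgst3, a microsomal glutathione transferase, higher (0.70 ± 0.15, adjusted p = 0.0346, lost without C57 animal 2, 3 or 4 or DBA animal 1, 2 or 3 at 0.0618 to 0.121, with median centring at 0.148 and without a filter on dim probe sets at 0.0708). Sdf4 was higher (2.19 ± 0.35) and the galactosyltransferase gene B3galt6 lower (mean log2 intensity 8.30 in C57 and 7.30 in DBA, adjusted p = 0.000368). The called sets of Prdx2 and Junb, given in the report with their other sets, also went apart.

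A candidate explanation is that neighbouring genes share a strain haplotype. Of 6556 neighbouring pairs of tested genes with different names, 14 had both genes called, against a median of 5 in 10000 shuffles of the 191 called genes (permutation p = 3e-04). A gene counted as called when any of its sets was, and in 6 of the 14 pairs the sets with the smallest p went the same way and in 8 they went apart. Order was taken from the RefSeq gene table of assembly GRCm38.p6, and the test does not separate linked differences in RNA level from linked sequence variants under the probes.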
